A study of Homo sapiens with 6 samples.

How the data were processed

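RNA of 6 cultures was measured, 3 of U87 and 3 of U87R, each on its own array of a human Agilent gene expression design read in 1 colour (Cy3). Group and replicate number were taken from the sample titles and descriptions. The labels call the samples biological replicates harvested after several passages. They do not say whether the cultures were kept apart before harvest, so p-values measure the spread between these samples, which may be partly technical.

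The deposited files hold spot intensity on a linear scale. Per the file headers they were made with Agilent Feature Extraction 11.0.1.1, and the grid refers to the genome build hg19. The submitters' processing notes name Agilent Feature Extraction 11.0 and R 3.3.3, with no role given for R. The processed intensity is, per the file headers, the authors' background-subtracted value, not scaled between arrays. Flags in the deposited files, of no unit, mark spots well above background, saturated spots and outliers. The deposited files lack the mean signal column, so the median signal took its place in the alternative background correction.

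Values were averaged over spots of a probe after log2, without control spots and outlier spots, which left 8 probes without a value on an array, and these were not used. From each array the 75th percentile of log2 signal over its 58201 non-control probes was subtracted. Between 41.8% and 45.3% of probes were well above background. Probes were named by the accession in the deposited files, without version, through a RefSeq gene table of assembly GRCh38.p14. Since that build differs from hg19, it served for names and for which genes neighbour each other, and no coordinates are given. A symbol was found for 31104 probes of 22439 genes, and 27097 probes stayed unnamed. A probe entered if it was well above background on the 3 arrays of at least 1 group, and the brightest probe stood for its gene, which left 14556 genes. The other 7883 genes were not tested. Of the tested genes, 16 that mark sex are in the counts and are not listed or drawn.

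Differences are U87R minus U87 on the log2 scale, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the genes tested), with an adjusted p under 0.05 as the threshold. For a gene above background in one group alone a lower bound is given. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own. The bound rests on the brightest probe alone, and other probes of a gene can differ less. Log2 differences of the probes ran from -9.41 to -2.58 for CSPG4, from -7.19 to -3.56 for ABCA1 and from -10.64 to -7.20 for HAS1. Those of PXDN lay closer, from 11.3 to 12.3. Gene lists were tested with camera at its preset correlation of 0.01, two-sided, adjusted over 45 lists with at least 5 measured genes. Lists, named-gene rule, tests and most other settings were fixed before the data were examined. The rule named the 12 largest increases and the 12 largest decreases among genes above background on all 6 arrays with no overlap between the groups, and the 4 largest bounds per direction. It added 15 fixed genes and up to 4 genes per list with the largest changes past the threshold, from which the text takes examples. Some genes of the rule are not reported here, and the alternatives for named genes leave them out. Genes of the closing section outside this rule were chosen after their values were seen. Lists that did not pass are given as member counts without a direction, a choice made after their medians were seen to change sign between settings.

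Slide and scan day, which coincide, were tested as a block and within each slide. Slide 1 held 2 arrays of each group and slide 2 held 1 of each. Deviations from the group means correlated between same-numbered arrays with r = 0.258, 0.361 and 0.448 for the 3 numbers, all over the limit of 0.1 set for pairing. Arrays of slide 1 with different numbers in the groups correlated with 0.248 and 0.408, so the pairing seen comes with the shared slide.

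Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter or a filter on all 6 arrays, the mean over probes, slide and replicate blocks, slide 1 alone, a variance trend with robust fitting, and array weights. Further ones left out each array in turn, tested against a 1.5-fold change with treat, and ran camera with estimated correlations and fry. After seeing the data 3 more were added: scaling to the probes above background on all arrays, averaging the arrays of one group and slide, and counting unnamed probes too.

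The test was tried on simulated data for this comparison, with the measured residual spread of the 14556 genes and 200 changed genes. It recovered 44 of the 100 genes changed by 1 on the log2 scale and 82 of the 100 changed by 2, with 8 false calls. The simulated noise was independent between arrays, without the slide effect of the data, and far fewer genes were changed than the 8271 called. These rates therefore do not describe the test as used on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.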

Results

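RNA from U87 cells, a human glioblastoma line, was compared with RNA from U87R, a line that the labels call resistant to temozolomide. Temozolomide is an alkylating drug used to treat glioblastoma. Each group had 3 arrays, labelled as biological replicates harvested after several passages, and each array measured 1 sample in 1 colour with 58201 probes. Between 41.8% and 45.3% of the probes were well above background on an array, and none was saturated. The number of arrays limits the precision. After naming and filtering, 14556 genes were tested. Replicates 1 and 2 of both groups lay on slide 1 and replicate 3 of both lay on slide 2, which was scanned on another day.

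The comparison of U87R with U87 asks which genes differ in expression between the resistant and the sensitive line. The product of the DNA repair gene MGMT removes some of the alkyl groups that temozolomide adds to guanine. MGMT was not well above background on any U87 array and was read on the 3 U87R arrays. Its level in U87R was at least 64.4-fold higher. GSTM3, a glutathione transferase, was likewise read in U87R alone and was at least 1215-fold higher there. HAS1, a hyaluronan synthase, was at least 1281-fold lower in U87R by its brightest probe. Of 29 hypoxia response genes 21 fell, of 12 genes in the metallothionein list 10 fell and of 25 cholesterol synthesis genes 19 rose. With an estimated correlation of their genes these lists did not pass (camera, adjusted p = 0.741, 0.741 and 0.279). Cholesterol synthesis was lost although its estimated correlation, -0.008, was below the preset 0.01. With estimated correlations camera also works on far fewer degrees of freedom. The difference reached 8271 of the 14556 genes tested (56.8%) at an adjusted p under 0.05, of which 3922 were higher and 4349 lower in U87R. The balance depended on the scaling, with 3390 higher and 5138 lower under median centring, and 4255 higher and 3918 lower when scaled to probes above background on all arrays.

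Among the genes past the threshold, 4852 had changed at least 2-fold, 2452 of them upwards and 2400 downwards. This count depended on the background correction, with 3236 under normexp correction, 1607 upwards and 1629 downwards. A set of 756 genes was above background on the 3 U87R arrays and on no U87 array, and 518 genes showed the opposite. Over the tested genes, Pearson's r between a U87 and a U87R array was 0.787 to 0.802. Within a group it was 0.997 to 0.998 for arrays of slide 1 and 0.983 to 0.986 across the slides. These correlations are across genes, which are not independent replicates. The first principal component, which parted the groups, held 93.1% of the variance, and the next, which parted the slides, held 4.46%. Fold changes measured on slide 1 and on slide 2 correlated with r = 0.961 across genes. Of the 8271 genes 8268 had the same sign on both slides, a count nearly set by the selection, since the same arrays called them. With slide as a block 10581 genes passed, and on slide 1 alone 11087 passed. The arrays of one group on slide 1 differed little from each other, and with those arrays averaged, so that each group had 1 value per slide, 5362 genes passed.

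**Figure D1:**
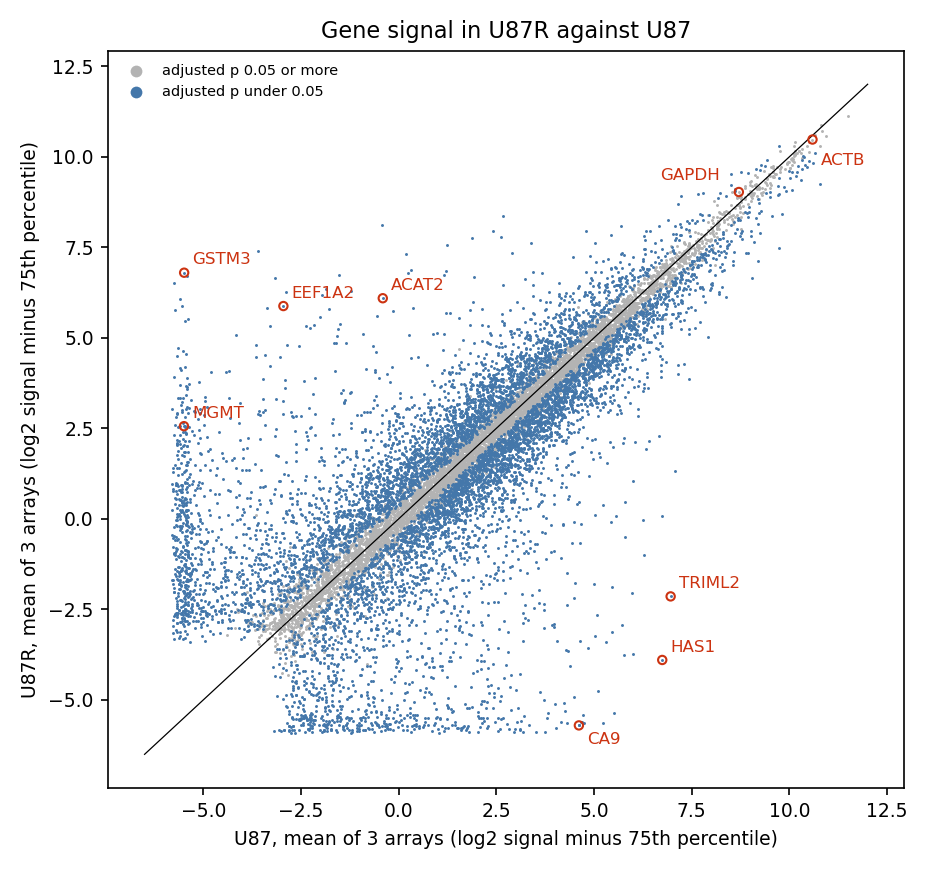
Mean log2 signal of each gene in U87R (vertical axis) against U87 (horizontal axis), both relative to the 75th percentile of the array, over 3 arrays per group. Blue points had an adjusted p under 0.05, the line marks equal signal, and GSTM3 and MGMT at the left edge were not well above background in U87, as CA9 at the bottom and HAS1 were not in U87R.

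Of the genes above background on all 6 arrays, the largest increases in U87R were those of EEF1A2, a translation elongation factor, at 8.82 ± 0.10 (SE) on the log2 scale, and COL18A1, a basement membrane collagen, at 8.54 ± 0.37. BST2, an interferon-induced membrane protein, followed with 8.25 ± 0.51. BMP7 rose by 8.20 ± 0.61, and TNFRSF11B, a decoy receptor of the TNF receptor family, rose by 8.14 ± 0.33. The increases of HSPA1A, GABRE, FBXL16, MMP1, IL4R, FBLN1 and SLC12A7 lay between 7.51 and 7.69, and HSPA1A cannot be told from its near-identical copy HSPA1B by name alone. The steepest decrease was that of TRIML2, at -9.10 ± 0.17. FABP5, a fatty acid-binding protein, changed by -8.64 ± 0.29, and IER3, an early response gene, by -8.02 ± 0.25. The decreases of RRAD, ACP5, EMILIN2, CGB3, RNF112, OCIAD2 and CTSK ran from -7.73 to -6.30. CGB3 belongs to a family of near-identical genes and is uncertain. The largest adjusted p among the genes named in this paragraph was 0.000133. Their sizes and order depended on the probe, since the probes of IER3 ran from -9.24 to -8.02, and on the background correction. Under normexp correction the increases ran from 5.64 for GABRE to 7.87 for COL18A1, with EEF1A2 at 6.88, and the decreases from -4.94 for RNF112 to -7.75 for TRIML2.

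Further genes were read in one group alone. Besides GSTM3, the neuronal pentraxin NPTX1 was at least 1151-fold higher in U87R, the peroxidasin PXDN at least 991-fold and the homeobox gene IRX1 at least 734-fold. Besides HAS1, the linker histone gene H1-1 was at least 545-fold lower in U87R, the myosin light chain MYL9 at least 452-fold and STXBP6 at least 409.7-fold. In each of these 8 genes the adjusted p was at most 2.18e-06.

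MGMT was measured by 1 probe, with a log2 signal of 2.56 ± 0.34 (SD, n = 3) in U87R and a background reading of -5.49 ± 0.19 in U87 (adjusted p = 5.14e-07). Of the 10 measured genes of direct reversal and alkyl damage repair, MGMT among them, 2 rose, 2 fell and 6 did not pass. The glycosylase MPG rose 2.80-fold, by 1.49 ± 0.22 on the log2 scale (adjusted p = 0.00136), and ALKBH1 changed by -0.74 ± 0.16. ALKBH1 did not pass with the arrays of one group and slide averaged (adjusted p = 0.0695). Of 22 genes of mismatch repair, the pathway that recognises the base pairs temozolomide leaves, 6 rose and 5 fell. PCNA was 1.26 ± 0.13 higher and MLH3 changed by -1.46 ± 0.13. MSH6 differed by 0.19 ± 0.11 (adjusted p = 0.176) and PMS2 by -0.17 ± 0.10 (adjusted p = 0.203), and neither passed. MSH6 passed under quantile normalization (adjusted p = 0.0480). The 5 probes of PMS2, which has many near-identical pseudogenes, ranged from -0.67 to 0.62.

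In base excision repair 8 of 20 measured genes rose and 5 fell, among them NTHL1, which rose by 1.47 ± 0.15. In homologous recombination and the Fanconi anaemia pathway 8 of 33 rose and 7 fell, with MRE11 at 1.59 ± 0.16 and RAD51B at -1.58 ± 0.20. Among 11 genes of non-homologous end joining, 2 rose and 1 fell, with TP53BP1 at 0.68 ± 0.11, which did not pass with the arrays of one group and slide averaged (adjusted p = 0.0518). Of 21 checkpoint signalling genes 6 rose and 2 fell, or 6 and 1 adjusted over the list alone, with the phosphatase CDC25B at 2.24 ± 0.16 and the histone H2AX at 1.81 ± 0.15. None of these 6 repair and checkpoint lists passed the list test (camera, adjusted p from 0.512 to 0.979).

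Other genes fixed in advance differed as follows. The drug efflux transporter ABCG2 rose 3.99-fold, by 2.00 ± 0.25 (adjusted p = 0.000671), while ABCB1 and the stem cell factor SOX2 were not well above background on any array. Of 11 measured genes in the list of ABC drug efflux transporters 5 rose and 3 fell, or 6 and 3 adjusted over the list alone. That list also holds transporters known mainly for lipids, such as ABCA1 and ABCA3, which both fell. ABCC3 was 2.54 ± 0.17 higher, ABCC2 changed by -4.19 ± 0.13, and ABCA1 was at least 69.2-fold lower by its brightest probe. The receptor EGFR was 0.82 ± 0.21 higher (adjusted p = 0.0162), by 1.09 on slide 1 and 0.26 on slide 2. Its call was lost with the probes of a gene averaged (adjusted p = 0.116), with the arrays of one group and slide averaged (0.137), and without U87 replicate 1 (0.0580), U87R replicate 1 (0.0547) or U87R replicate 2 (0.0580). GAPDH differed by 0.32 ± 0.24 (adjusted p = 0.304), and passed with slide (adjusted p = 0.00696) or replicate number (0.0259) as a block. ACTB differed by -0.11 ± 0.13 (adjusted p = 0.485), and by 0.10 under quantile normalization. On slide 1 alone GAPDH (adjusted p = 0.00535) and ACTB (0.0258) passed. With array weights MSH6, PMS2, GAPDH and ACTB passed, with adjusted p from 0.00221 to 0.0334.

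**Figure D2:**
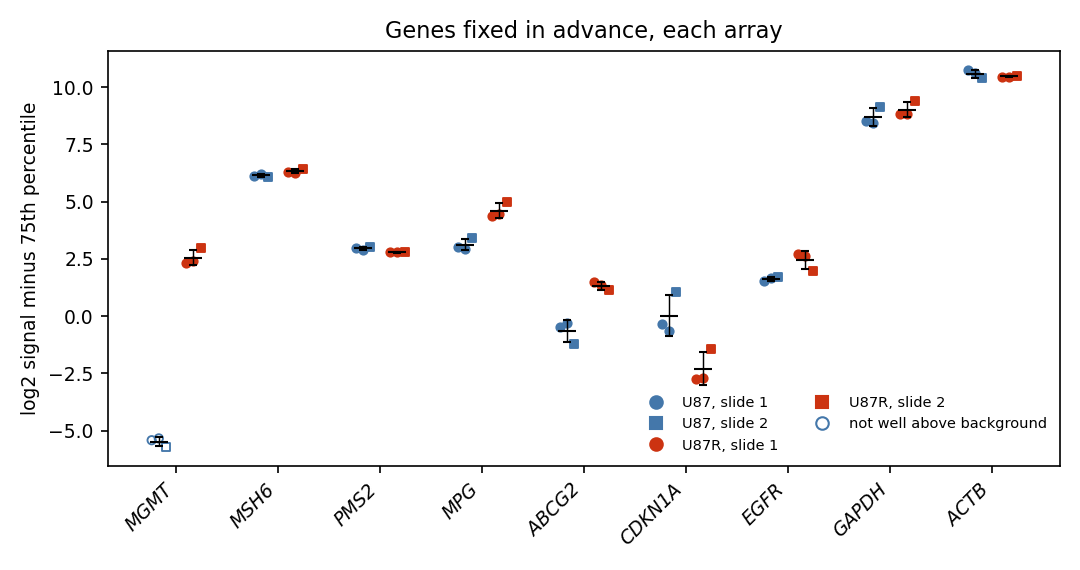
Log2 signal relative to the 75th percentile of the array (vertical axis) for 9 genes fixed in advance (horizontal axis), in U87 (blue) and U87R (red). Circles are arrays of slide 1, squares slide 2, open symbols readings not well above background and bars the mean ± SD of 3 arrays, and MGMT goes from background in U87 to 2.56 in U87R, while MSH6 and PMS2 differ by 0.19 and -0.17.

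CDKN1A, a p53 target that restrains the cell cycle, changed by -2.32 ± 0.54 (adjusted p = 0.0104). Of 28 measured p53 target genes 5 rose and 17 fell, with a median log2 difference of -0.86. TP53INP1 changed by -2.96 ± 0.17 and PHLDA3 by -2.84 ± 0.20, and SPATA18 was at least 9.37-fold lower. The list passed as lower (camera, adjusted p = 0.0427) but not with an estimated correlation (adjusted p = 0.741). Its median was -0.82 on slide 1 and -1.04 on slide 2. It did not pass with slide (adjusted p = 0.0701) or replicate number (0.0641) as a block, without U87 replicate 3 (0.0803) or without U87R replicate 3 (0.0555). Nor did it pass under normexp correction, quantile normalization, median centring, the filter on all 6 arrays, the mean over probes, slide 1 alone or array weights (adjusted p from 0.0514 to 0.0957).

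Among 35 genes of mitosis and G2/M, 4 rose and 14 fell (3 and 11 adjusted over the list alone), with CCNA2 at -0.98 ± 0.20 and KIF20A at 0.98 ± 0.16. Of 33 genes of G1/S and DNA replication 8 rose and 4 fell (5 and 4 adjusted over the list alone), with GINS1 at 1.75 ± 0.13 and MCM6 at -0.97 ± 0.12. Neither list passed (adjusted p = 0.304 and 0.765).

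Of 29 measured genes of the hypoxia response 2 rose and 21 fell, or 2 and 23 adjusted over the list alone. Its median difference was -1.62, with -1.43 on slide 1 and -1.45 on slide 2. The carbonic anhydrase CA9 was at least 292-fold lower in U87R and the aldolase ALDOC at least 47.9-fold lower. VEGFA, a growth factor for blood vessels, changed by -3.30 ± 0.26, and LOX, which crosslinks collagen, by -3.44 ± 0.21. The list passed (camera, adjusted p = 0.000110), but with an estimated correlation of its genes the adjusted p was 0.741. Of 19 glycolysis genes 2 rose and 8 fell (2 and 10 adjusted over the list alone), with ENO2 at -2.81 ± 0.16 and HK2 at -1.62 ± 0.30, and the list did not pass (adjusted p = 0.272).

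Of 25 measured genes of cholesterol synthesis 19 rose and 2 fell, with a median difference of 1.16, and of 1.16 on slide 1 and 1.03 on slide 2. ACAT2, an acetyl-CoA acetyltransferase, rose by 6.50 ± 0.17, MVD by 3.15 ± 0.15 and HMGCS1 by 2.29 ± 0.12. The list passed (camera, adjusted p = 9.86e-05), with an adjusted p = 0.279 with an estimated correlation.

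Metallothioneins are small proteins that bind zinc and copper. Of 12 measured genes in their list, which was fixed with the zinc transporter SLC30A1 as a further member, 10 fell and 0 rose. MT1G was at least 28.4-fold lower, MT1F changed by -4.37 ± 0.25, MT1M by -3.55 ± 0.22 and MT1E by -2.40 ± 0.12. These genes are near-identical in sequence, so the share of each is uncertain. The median was -1.46, with -1.49 on slide 1 and -1.40 on slide 2. Camera gave an adjusted p = 0.000606 for the list, and 0.741 as the adjusted p with an estimated correlation.

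Genes of glutathione metabolism and NRF2 targets rose in 18 of 31 measured members and fell in 6, with a median difference of 1.20, and of 1.18 on slide 1 and 1.08 on slide 2. After GSTM3, the glutathione peroxidase GPX3 was at least 74.3-fold higher. The aldo-keto reductases AKR1C3 and AKR1C1 rose by 6.33 ± 0.29 and 5.88 ± 0.44, although their sequences are too alike to be sure of each. The list passed (camera, adjusted p = 0.0427), and with an estimated correlation its adjusted p was 0.741. It was lost without U87R replicate 3 (adjusted p = 0.0552) and with array weights (0.0751). Of 14 aldehyde dehydrogenases 8 rose and 4 fell, with ALDH3A1 at least 175-fold higher and ALDH1L2 at least 20.3-fold lower, and the list did not pass (adjusted p = 0.287).

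The type I interferon response rose in 17 of 35 measured genes and fell in 9, or 18 and 9 adjusted over the list alone. IFITM1 was at least 554-fold higher in U87R and CMPK2 at least 4.65-fold higher, while HERC5 changed by -3.33 ± 0.22. The median difference was 0.56, with 0.34 on slide 1 and 0.94 on slide 2. The list passed (camera, adjusted p = 0.0427), but not with an estimated correlation (adjusted p = 0.741), with slide (0.0562) or replicate number (0.0641) as a block, or without U87R replicate 3 (0.0832). It was also lost under quantile normalization (adjusted p = 0.0515), array weights (0.0751) and scaling to probes above background on all arrays (0.0568). Of 23 antigen presentation genes 4 rose and 11 fell, among the latter HLA-DPB1 at -3.96 ± 0.20 and HLA-DRA at -2.66 ± 0.29, with an adjusted p = 0.287 for the list. HLA class II genes resemble each other and are uncertain.

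WNT pathway genes rose in 14 of 29 measured members and fell in 4. NKD2 was at least 84.1-fold higher, the receptor LRP5 at least 30.8-fold and the WNT antagonist SFRP1 at least 17.4-fold, and DKK3 rose by 6.61 ± 0.56. NKD2 and SFRP1 are known as inhibitors of the pathway. The median difference was 0.42, with 0.24 on slide 1 and 0.78 on slide 2. The list passed (camera, adjusted p = 0.0427), but not with an estimated correlation (adjusted p = 0.741), nor with slide (0.0701) or replicate number (0.0657) as a block, without U87 replicate 3 (0.0912) or without U87R replicate 3 (0.0578). Quantile normalization, no filter, the filter on all 6 arrays, slide 1 alone and array weights ended the call too (adjusted p from 0.0515 to 0.128). NOTCH pathway genes rose in 8 of 17 and fell in 2, with NRARP at least 28.7-fold and DLL1 at least 16.5-fold higher, and the list did not pass (adjusted p = 0.287).

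Immediate early genes, which cells switch on within minutes of a growth signal, rose in 2 of 28 measured members and fell in 13. EGR2 changed by -3.99 ± 0.35 and DUSP6 by -3.48 ± 0.52. The median difference was -1.0, with -1.16 on slide 1 and -1.03 on slide 2. Camera gave an adjusted p = 0.0427, and with an estimated correlation an adjusted p = 0.780. The call was lost without U87 replicate 3 (adjusted p = 0.158), U87R replicate 1 (0.0585) or U87R replicate 2 (0.0618). It was also lost under quantile normalization, median centring, no filter, the mean over probes and array weights (adjusted p from 0.0515 to 0.0913).

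Genes of the cell surface, the matrix and secreted signals changed in both directions. Mesenchymal transition genes rose in 5 of 28 and fell in 16 (6 and 16 adjusted over the list alone), with ACTA2 at -5.51 ± 0.34 and TNC at -5.34 ± 0.16. Collagens and matrix genes rose in 13 of 34 and fell in 10 (14 and 10 adjusted over the list alone), with NID1 at least 144-fold and COL4A1 at least 100.4-fold higher. Of 27 integrins and adhesion genes 10 rose and 12 fell, with the cadherin CDH6 at least 111-fold higher and NCAM1 at least 72.7-fold lower. NF-kB targets and inflammatory cytokines rose in 7 of 28 and fell in 16 (8 and 17 adjusted over the list alone), with CXCL1 at least 169-fold lower and CXCL2 at -6.30 ± 0.59. Growth factor receptors and ligands rose in 15 of 35 and fell in 12 (16 and 12 adjusted over the list alone), with EREG at least 104-fold lower and FGFR3 at least 25.6-fold higher. Among IGF-binding proteins and TGF-beta/BMP genes 16 of 35 rose and 13 fell, with IGFBP5 at least 640.5-fold higher and GREM1 at least 111-fold lower. These 6 lists did not pass (adjusted p from 0.251 to 0.905).

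**Figure D3:**
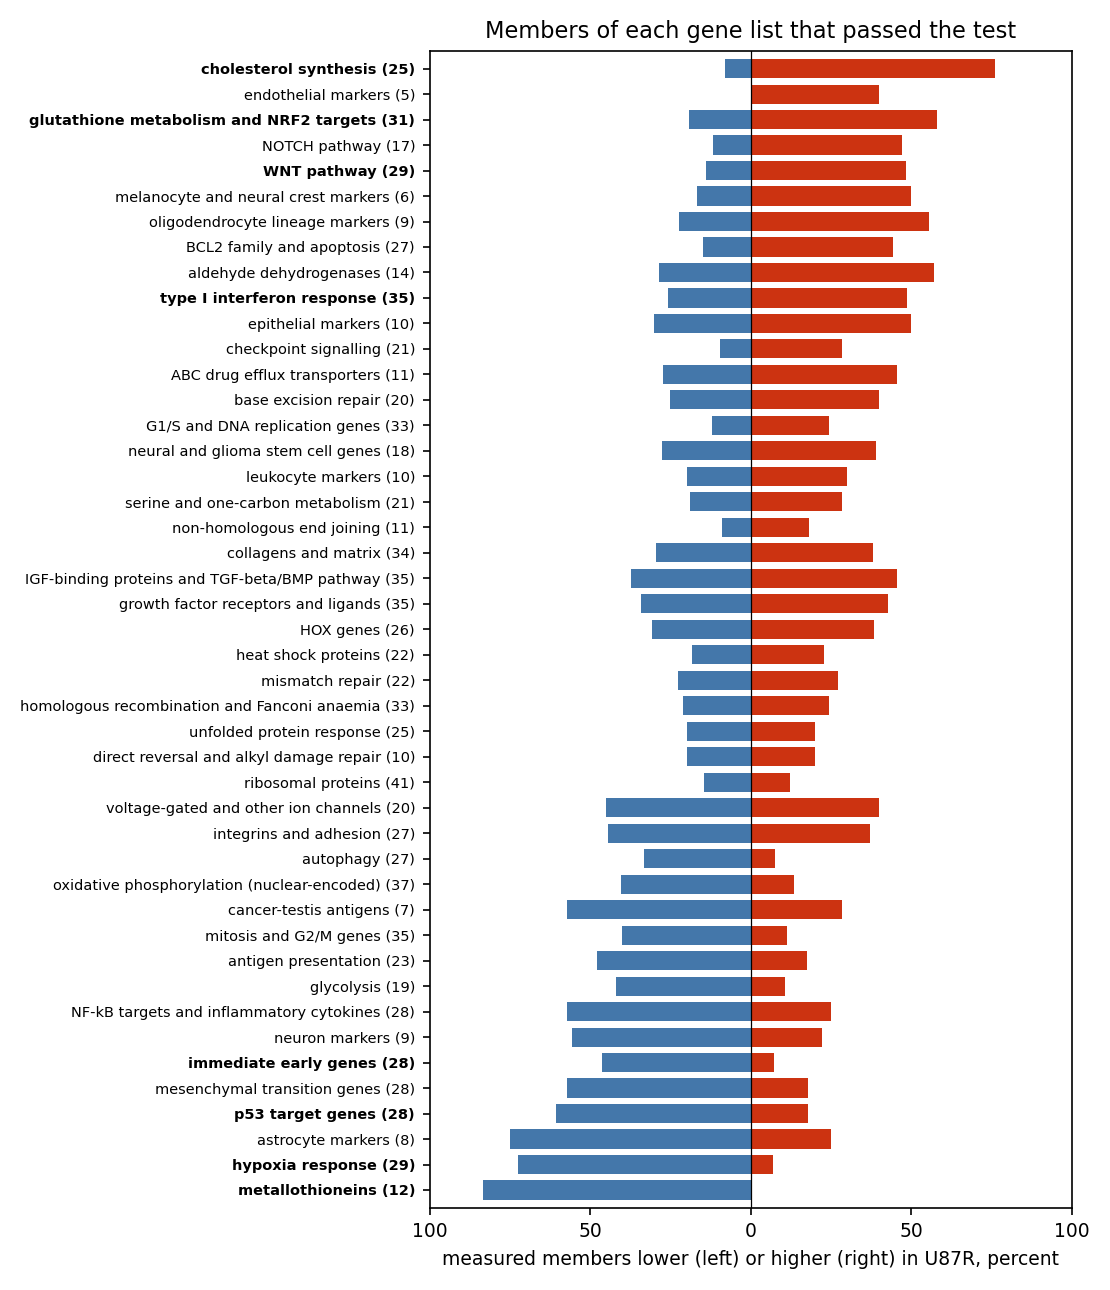
Percent of the measured members of each of 45 gene lists (vertical axis, measured members in parentheses) that were higher (red, right) or lower (blue, left) in U87R at an adjusted p under 0.05. Bold names mark the 8 lists that passed camera with its preset correlation, from cholesterol synthesis with 19 of 25 genes higher to metallothioneins with 10 of 12 lower.

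With the preset correlation 8 of the 45 lists passed, and with estimated correlations 0 passed. For the hypoxia response and metallothioneins the estimates, 0.255 and 0.41, were above the preset 0.01, but for cholesterol synthesis the estimate was -0.008. A stronger correlation of its genes therefore does not account for the loss of that call. With estimated correlations camera also tests on the residual degrees of freedom of 6 arrays in 2 groups, far fewer than with the preset. A call lost in that setting is thus no sign of correlation alone. The limma function fry, which does not compare a list with other genes, gave 38. The counts adjusted over the list alone equalled those over all genes tested in 29 lists, and the others stand beside their counts. The list counts say nothing of lists against each other.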

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

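The tests of the extent of the difference by slide and by scaling were chosen after the result was seen, and the count of other splits was fixed before. Groups of 3 arrays were not tested for single deviating samples.

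A signal was seen in data outside the comparison of named genes. Among the probes with no matched symbol, 517 were well above background on the 3 U87R arrays and on no U87 array, and 308 showed the opposite. Of 6542 unnamed probes that met the filter, 2467 passed the limma test (adjusted p under 0.05), 1359 higher and 1108 lower.

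The extent of the difference between U87R and U87 is a pattern that a biologist would want to follow up: 8271 of 14556 genes passed, 756 genes were read in U87R alone and 518 in U87 alone. Slide and scan day as the cause would give different fold changes on each slide, whereas those of slide 1 and slide 2 correlated with r = 0.961 over genes. Each slide held arrays of both groups, so the design already kept slide and scan day apart from the group. The correlation adds to this only that the difference was repeated on both slides. Array scaling as the cause would end most calls, whereas 7936 calls kept their sign under quantile normalization. The real split called 8271 genes with limma and the highest of the other splits 0, with at most 527 at an unadjusted p under 0.05, but 1 of 10 splits is the smallest share the design allows, so the splits are too few for a share under 0.05. This also holds against the 3 other splits that part the pairs as the real one does, which called 0 genes. Every split but the real one mixed U87 with U87R arrays, which puts the group difference into the residual spread. Their 0 calls were thus nearly fixed in advance. Changes selected under temozolomide, drift over passages and a U87R culture of other origin stay open and were not tested, since RNA levels alone give no test of descent.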

How the results depend on the processing

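The alternatives chosen after the data were seen were scaling to probes above background on all arrays, averaging arrays of one group and slide, and counting all probes. Of 102 alternative values of the counts, 85 stayed within 1.5 times. The 3236 genes changed at least 2-fold under normexp correction did so only just. Of 1710 alternative values of the list member counts, 201 moved further: 2 to 13 for each array left out, 32 with arrays of one group and slide averaged, 26 with array weights, 22 with only probes above background on all arrays and 16 with slide as a block. With only probes above background on all arrays 12592 genes entered, against 14556, and 3202 changed at least 2-fold, against 4852. That filter leaves out the genes read in one group alone. Array weights, which favour slide 1, gave 6550 lower genes. Averaging arrays of one group and slide gave 5362 changed and 2700 lower genes, with fewer samples. All probes gave 13311 changed, 6460 higher, 6851 lower and 8228 changed at least 2-fold, over more features. Against a 1.5-fold change 4455 genes passed. Of the list tests 4 passed under quantile normalization, 5 with slide as a block and 5 with the replicate number as a block. Array weights gave 3, estimated correlations 0 and fry 38. Beyond fry's other question and the fewer degrees of freedom with estimated correlations, the cause was not tested. With 1 array left out, 4 to 8 lists passed (5 without U87 replicate 3, 4 without U87R replicate 3), 6970 to 8686 genes changed, 3361 to 4064 were higher, 3586 to 4622 lower and 4736 to 4878 changed at least 2-fold. The replicate block, used for the paired numbers, gave 9726 changed genes; it changed the calls given beside p53 targets, interferon, WNT and GAPDH, and moved 8 list member counts, such as homologous recombination to 13 lower and ribosomal proteins to 10 lower. Of 3865 alternative values of named genes 3735 kept direction and side, 36 lost and 9 gained the threshold, 84 moved on slide 2 without a test, and 1 reversed without a call, ACTB at 0.10 under quantile normalization, for which the cause was not tested. Of 8 passing lists 0 changed the sign of the median, and 17 of the 37 others did under some alternative. Median centring moved the median of all genes from -0.06 to -0.20, so small changes are read relative to that shift. Genes under background in a group have bounds only, and 7883 genes gave no test.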

Other observations

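The tests of the MTAP neighbourhood and of the zinc finger runs were chosen after the result was seen, and the limits on the MTAP shuffles and on the spread of the zinc finger levels were made stricter, and the test for loss of DNA replaced, after their values were seen.

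Members of further gene lists changed in both directions, and the lists did not pass. HOX genes rose in 10 of 26 measured members and fell in 8, with HOXC13 at least 86.5-fold and HOXA13 at least 46.2-fold higher in U87R, and HOXB2 changed by -8.24 ± 0.38, with 2 of 3 U87R arrays above background. Ion channel genes rose in 8 of 20 and fell in 9, with the calcium channel CACNA1A at least 95.1-fold lower. Neural and glioma stem cell genes rose in 7 of 18 and fell in 5 (8 and 5 adjusted over the list alone), with nestin (NES) at -5.60 ± 0.25 and ITGA6 at 3.33 ± 0.40. Serine and one-carbon metabolism rose in 6 of 21 genes and fell in 4, with the transporter SLC7A5 at 3.79 ± 0.36 and CBS at 3.12 ± 0.41. BCL2 family and apoptosis genes rose in 12 of 27 and fell in 4, with BOK at least 38.7-fold higher. Autophagy genes rose in 2 of 27 and fell in 9, with GABARAPL1 at 2.70 ± 0.23 and BNIP3 at -1.99 ± 0.23. The unfolded protein response had 5 of 25 genes up and 5 down (4 and 5 adjusted over the list alone), with DDIT3 at -2.42 ± 0.19. Heat shock proteins rose in 5 of 22 and fell in 4 (3 and 3 adjusted over the list alone), with HSPB3 at -5.51 ± 0.19. Of 37 nuclear-encoded oxidative phosphorylation genes 5 rose and 15 fell, with COX6A1 at -1.17 ± 0.11, and of 41 ribosomal protein genes 5 rose and 6 fell (5 and 3 adjusted over the list alone). Cancer-testis antigens rose in 2 of 7 and fell in 4, with MAGEA1 at least 7.15-fold higher.

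Markers of cell types were fixed as further lists. Astrocyte markers rose in 2 of 8 and fell in 6, with GJA1 at -3.49 ± 0.35 and SOX9 at 2.12 ± 0.23. Oligodendrocyte lineage markers rose in 5 of 9 and fell in 2 (5 and 3 adjusted over the list alone). PDGFRA was at least 15.6-fold higher, and CSPG4 was at least 267-fold lower by its brightest probe. Neuron markers rose in 2 of 9 and fell in 5, with GAP43 at least 7.69-fold lower. Epithelial markers rose in 5 of 10 and fell in 3, with the keratin KRT18 at 5.65 ± 0.12. Leukocyte markers rose in 3 of 10 and fell in 2, endothelial markers rose in 2 of 5 and fell in 0, and melanocyte and neural crest markers rose in 3 of 6 and fell in 1, with TFAP2A at 3.41 ± 0.28. None of the lists in these paragraphs passed camera (adjusted p from 0.287 to 0.979). Median, mean and test differed in sign in 12 of the 45 lists and in 0 of the 8 that passed: direct reversal, homologous recombination, G1/S, ABC transporters, stem cell genes, integrins, the unfolded protein response, ion channels, cancer-testis antigens, serine metabolism, oligodendrocyte and leukocyte markers.

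Genes near MTAP, which lies next to the tumour suppressor CDKN2A, were read in U87R alone. Of 7 tested neighbours from MLLT3 to CDKN2B, 5 were off in U87: KLHL9 was at least 189-fold higher in U87R, FOCAD at least 163-fold, MTAP at least 44.4-fold, MLLT3 at least 5.55-fold and CDKN2B at least 1.92-fold. In 44 of 1000 shuffles of the gene order, 5 or more such genes appeared among 7 neighbours, zinc finger genes not counted. The shuffles spread the state over all protein-coding genes, at 615 of 12923. Outside the zinc finger family 520 of 12478 had it, so 44 is on the high side. Since the window was set after its genes were seen, silencing at unrelated positions cannot be told apart from a shared cause. Loss of this DNA in U87 is consistent with the 5 silent genes, but 2 of the 7 were read on the U87 arrays, IFNA4 at -2.70 and CDKN2A at 1.06, against -2.64 and 1.00 in U87R. A second CDKN2A probe was not above background in either group, so those readings may come from other transcripts, and lost and silenced genes stay open.

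The longest runs of neighbouring genes read in U87R alone were of zinc finger genes, and the family was counted for that reason. Fisher's test was run on its share and is not used, because the family was picked from these runs and neighbouring genes are not independent. Of 445 zinc finger genes 95 (21.4%) were read in U87R alone, against 520 of 12478 other protein-coding genes (4.17%), and 7 (1.57%) were read in U87 alone, against 438 (3.51%). Neighbours in the order of tested protein-coding genes shared this state, in runs of 10, 7 and 6 genes. Untested genes may lie between them. The run of 10 held ZFP82, ZNF566, ZNF260, ZNF529, ZNF382, ZNF461, ZNF567, ZNF850, ZNF345 and ZNF568. The run of 7 counted ZNF816 and the read-through ZNF816-ZNF321P as separate genes. A property of the gene family without position would give such runs by chance, whereas 0 of 1000 shuffles among zinc finger genes gave a run of 10, and the longest was 7. The runs of 7 and 6 were thus within reach of the shuffles. Every zinc finger gene had the same chance in the shuffles, so a property of a subgroup whose genes lie together was not excluded. Signals near the detection limit would give small bounds, whereas the median bound over the 10 genes was 8.97-fold, from 1.76-fold to 82.6-fold. Cross-hybridisation between paralogs stays open, since levels in U87R varied over the 10 genes with an SD of 1.84 log2 units, which unequal cross-hybridisation could also give; silencing of whole clusters in U87 is therefore a hypothesis only.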
